A study of Homo sapiens with 6 samples.

How the data were processed

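RNA-seq libraries were made from total RNA of A2780 cells, 3 control and 3 given citric acid at 8 mM, and each sample's group was taken from its treatment label. Per the submitters' processing notes, reads were handled with cutadapt, HISAT2 and StringTie, with no versions, on the build hg19. The authors deposited 1 table of 60612 genes with Ensembl identifiers, coordinates, functional annotations, and 2 kinds of value per library. The FPKM values deposited by the authors are fragment counts scaled for transcript length and library size, and a gene with a count of 0 is listed at 1e-04 FPKM. The counts deposited by the authors are whole numbers per gene without normalization. How the counts were made from the StringTie output is not given in the sources used here. Of counts from 1 to 40, 35.3% were multiples of 4, against 25% of the integers, so a count need not be a single read pair, and count-based limits cover counting error only and overstate the precision. Of the 58394 gene identifiers shared with GENCODE v29, 99.98% overlapped the GRCh38 position of that gene and 90.6% shared a start or end, so the coordinates printed are read as GRCh38 although the processing notes name hg19.

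Total counts ranged from 57290287 to 71567476 per library. A count of 0 allows up to 3 counts, 0.0419 to 0.0524 CPM. No pair of libraries agreed within sampling noise: after division of the counts by 4, chi-square per gene was 13.3 to 14.7 within groups and 36.0 to 39.2 between groups. In 27 genes of the control group and 26 of the citric acid group, 1 library had a count of 0 and the other 2 at least 50, so single-gene estimates can be unstable.

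The comparison of citric acid with control was made on the counts with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjustment over 19321 genes). The design fixed before the data were examined named limma on log2(FPKM + 1), or edgeR if raw counts were present. The deposited counts were taken as raw counts, although how they were made is not given. A gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. FPKM are given as mean ± SD of 3 libraries. The common biological coefficient of variation was 0.252. On simulated counts over 18664 genes with known changes, the edgeR step recovered 14% of 1.5-fold, 44% of 2-fold, 72% of 4-fold and 74% of 8-fold changes, with 4 false calls. Few of the simulated genes were changed, against 24.1% of genes called in the real comparison. The adjusted threshold was therefore stricter in the simulation, and these shares are not the sensitivity of the real test.

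A set of 31 gene lists, fixed before the data were examined, was tested with camera (limma 3.58.1) on log2(FPKM + 1) of the tested genes with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. This test was repeated with an estimated correlation, which called 4 lists, and fry was run beside it, which called 25. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. Where a name had several rows, the row with the highest mean was used. The genes named were fixed by a rule. It took the 12 largest rises and falls with adjusted p under 0.05, at least 5 FPKM in the higher group, no overlap between groups and a gene symbol. It added CASP1, CASP4, TXNIP, NLRP3, GSDMD, GSDME, PYCARD, IL1B and IL18 at any value, the 4 tested members with the smallest p of each called list, and up to 2 called members of each other list. A gene that the rule took is not reported here. KEGG and GO annotations of the table were tested by Fisher's exact test, one-sided, for terms of 10 to 300 genes, against the tested genes with an annotation of that source.

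Alternatives fixed beforehand were DESeq2 1.42.0 on the counts, edgeR without its filter, limma on log2(FPKM + 1) with a mean FPKM of at least 1, and the replicate number as a block. They also covered summing rows of the same name and leaving out each library. For limma they covered a pseudocount of 0.1, no filter, a mean FPKM of at least 5, and robust eBayes without trend. Limma was also run after TPM, median-ratio and quantile scaling. Added after the data were seen were RLE factors, library size alone, removal of mitochondrial genes, counts divided by 4, robust dispersion fits and camera on log2 CPM. GC content and length were those of the longest GENCODE v29 transcript of each gene.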

Results

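Transcript levels were measured by RNA-seq in A2780 cells, an established human ovarian cancer cell line. The series holds 3 control libraries and 3 libraries from cells given citric acid at 8 mM. Citric acid is the tricarboxylic acid formed in the first step of the citrate cycle, and the title of the series links it to pyroptosis, an inflammatory form of cell death carried out by gasdermin pores, through caspase-4, TXNIP, NLRP3 and GSDMD. Total counts were 57290287, 62493675 and 71567476 in control replicates 1 to 3, and 63040836, 65079012 and 62903668 in citric acid replicates 1 to 3. The first principal component held 36.5% of the variance and separated the groups. The share of counts from the mitochondrial genome was 15.4 ± 0.57% in control and 17.7 ± 0.25% in citric acid (SD, n = 3 each), without overlap. The labels do not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

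Citric acid was accompanied by a broad change of the transcriptome. TXNIP rose 11.3-fold, targets of the hypoxia factor HIF and glycolytic genes fell together, nucleolar and DNA replication genes fell by less, and interferon-stimulated genes and p53 targets rose. With an estimated correlation between genes, the list calls of HIF targets and of interferon-stimulated genes were lost (camera adjusted p = 0.0707 each). Of 19321 genes tested, 4660 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2182 higher and 2478 lower in citric acid. Which direction held more genes depended on the scaling: edgeR with library size alone gave 2485 higher and 2168 lower, and limma on FPKM rescaled to TPM 1477 and 2620. Most of these changes were small: 2821 were under 1.5-fold, and the median size was 0.49 on the log2 scale. At least 2-fold changes were found in 786 genes, 500 higher and 286 lower. With limma on log2(FPKM + 1) the 2-fold changes were 60 higher and 62 lower, with a pseudocount of 0.1 they were 173 and 117, and after TPM, median-ratio and quantile scaling 84 and 119, 45 and 72, and 49 and 67. The series' design text states 899 differentially expressed genes, 585 higher and 314 lower, without the rule. An unadjusted p under 0.05 with at least a 2-fold change gave 1192 genes in edgeR, 755 higher and 437 lower. The 3 libraries of each group did not overlap in 43.6% of the tested genes, where chance gives 10%.

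Among genes of pyroptosis and the inflammasome, TXNIP and the caspases CASP4 and CASP1 rose, while the transcripts of NLRP3, GSDMD, PYCARD and IL1B were at or near 0 in both groups. TXNIP, an arrestin-like protein that binds thioredoxin (ENSG00000265972, chromosome 1, 145992435 to 145996579), rose from 1.20 ± 0.084 to 14.1 ± 0.31 FPKM (SD, n = 3 each), a log2 fold change of 3.50 ± 0.082 (SE; edgeR adjusted p = 7.72e-05). CASP4, the inflammatory caspase that senses cytosolic lipopolysaccharide (ENSG00000196954, chromosome 11, 104942866 to 104969366), rose from 1.59 ± 0.25 to 4.29 ± 0.36 FPKM, a log2 fold change of 1.39 ± 0.13 (edgeR adjusted p = 0.00105). CASP1, the caspase that matures interleukin-1 beta (ENSG00000137752, chromosome 11, 105025443 to 105035250), rose from 6.92 ± 0.17 to 9.35 ± 0.45 FPKM, by 0.39 ± 0.059 on the log2 scale (edgeR adjusted p = 0.00544). Coordinates are those of the deposited table, which lie on GRCh38.

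The counts of GSDMD, the gasdermin cut by these caspases (ENSG00000104518, chromosome 8, 143553207 to 143563062), were 0, 2 and 15 in the control libraries and 18, 8 and 10 in the citric acid libraries. Its log2 fold change of 1.12 ± 1.13 did not pass the test (edgeR adjusted p = 0.533), and a difference was not detectable at this depth. NLRP3, the inflammasome sensor, had counts of 0, 12 and 0 in control and 8, 0 and 0 in citric acid. PYCARD, the inflammasome adaptor, and IL1B had a count of 0 in all 6 libraries, which allows up to 0.0419 to 0.0524 CPM in a library. IL18 had counts of 8, 0 and 0 in control and 8, 35 and 32 in citric acid, below the filter for testing. GSDME, the gasdermin cut by caspase-3, was at 2.29 ± 0.59 FPKM in control and 3.27 ± 0.28 FPKM in citric acid, with a log2 fold change of 0.47 ± 0.20 that did not pass the test (edgeR adjusted p = 0.152).

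**Figure D1:**
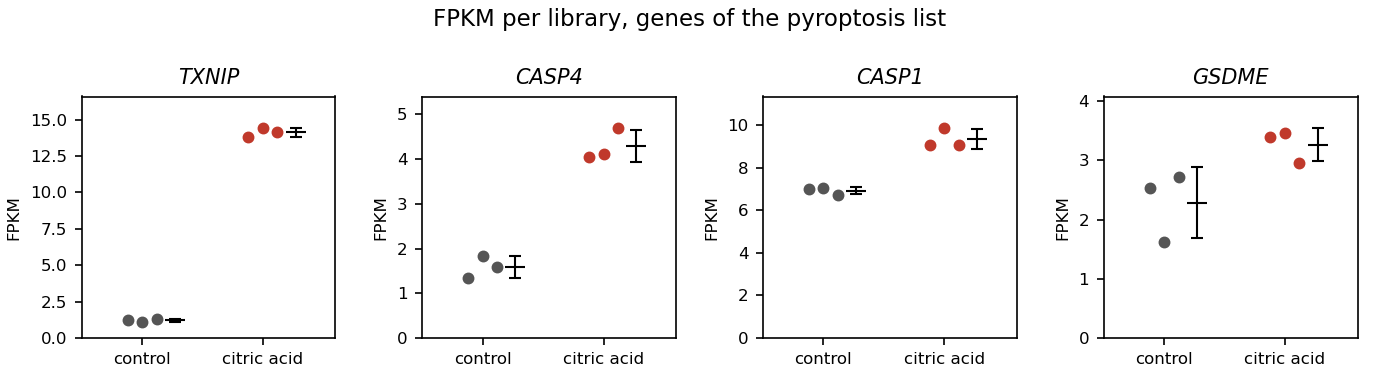
FPKM (linear axes from 0) of TXNIP, CASP4, CASP1 and GSDME in each of the 3 control (grey) and 3 citric acid (red) libraries, with the group mean and SD as black bars. TXNIP lies near 1.20 FPKM in control and near 14.1 FPKM in citric acid, and the groups do not overlap for any of the 4 genes, though GSDME did not pass the test.

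Over the whole list, 5 of 18 tested members passed the test, 3 higher and 2 lower, and adjusted over the list alone 4 were higher and 4 lower. The 2 lower genes, named after their values were seen, were GSDMB, a gasdermin family gene, with a log2 fold change of -0.75 ± 0.21 (edgeR adjusted p = 0.0458), and PANX1, a membrane channel gene, with -0.39 ± 0.078 (edgeR adjusted p = 0.0145). Without citric acid replicate 1 or without citric acid replicate 3 the count was 3, none of them lower. Of all tested genes 24.1% passed the same test. The list as a whole did not stand apart from the other genes (camera adjusted p = 0.197). Fry, which makes no comparison with other genes, called it higher (adjusted p = 8.63e-05).

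Further large rises were found for EMP1, a membrane protein gene that went from 39.5 ± 3.1 to 180 ± 4.2 FPKM with a log2 fold change of 2.14 ± 0.067 (edgeR adjusted p = 0.000138). SUOX, the gene of sulfite oxidase, rose by 2.54 ± 0.15 on the log2 scale from 1.74 ± 0.35 FPKM. ID1, an inhibitor of basic helix-loop-helix factors, rose from 24.3 ± 2.8 to 76.5 ± 5.6 FPKM, with a log2 fold change of 1.61 ± 0.096. CLIP3, PBXIP1, TRAPPC6A and LINC02154 rose by 1.51, 1.46, 1.43 and 1.41 on the log2 scale. The other rises among the 12 largest are uncertain. RPL13AP7 and RPSAP54 are ribosomal pseudogenes and RNASEK-C17orf49 is a readthrough locus, and reads of such loci may belong to related genes, which was not tested here. DAG1 had 44.1, 5.88 and 46.8 FPKM in citric acid replicates 1 to 3. Leaving out single libraries ended the calls of RPL13AP7, DAG1 and RPSAP54, with edgeR adjusted p of up to 0.0886, 0.105 and 0.0679.

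Among the 12 largest falls, CA9, the gene of the membrane carbonic anhydrase IX, fell from 13.2 ± 1.7 to 1.33 ± 0.66 FPKM, with a log2 fold change of -3.33 ± 0.41 (edgeR adjusted p = 0.00274). BHLHE40, a transcriptional repressor gene, fell from 20.2 ± 0.99 to 5.15 ± 0.28 FPKM, with a log2 fold change of -2.01 ± 0.070. RAB20, ANGPTL4, DANCR, HK2 and TLCD3A had log2 fold changes of -2.21, -1.85, -1.83, -1.80 and -1.79. UPK1A and UPK1A-AS1, at -1.94 and -2.48, lie on the same stretch of chromosome 19, and reads of the pair may be mixed, which was not tested here. The call of HILPDA, a lipid droplet gene at -1.95, ended without control replicate 1, 2 or 3 (edgeR adjusted p of up to 0.0630). The call of UNC13A, at -2.15, ended without citric acid replicate 1, 2 or 3 (up to 0.0593). PPAN-P2RY11, a readthrough locus, at -5.86, lost its call without any of 4 libraries (up to 0.112).

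HIF target genes fell almost throughout. Of 26 tested, 24 were lower and none higher, also adjusted over the list alone, with a median log2 fold change of -1.04. SLC2A1, the glucose transporter GLUT1, fell from 14.6 ± 0.60 to 4.64 ± 0.23 FPKM (-1.69 ± 0.060 on the log2 scale), BNIP3, a mitophagy receptor, from 36.2 ± 0.68 to 15.5 ± 0.83 FPKM and PGK1 from 165 ± 3.3 to 88.4 ± 3.2 FPKM. The glycolysis list had 18 of 22 tested genes lower and none higher, 20 adjusted over the list alone, with a median of -0.92. HK2, hexokinase 2, went from 25.4 ± 1.3 to 7.53 ± 1.6 FPKM and PFKP, a phosphofructokinase, from 28.3 ± 0.78 to 12.7 ± 0.12 FPKM. SLC2A3, the glucose transporter GLUT3, fell by 1.01 on the log2 scale. GAPDH, often used as a reference gene, fell from 1672 ± 16.5 to 1036 ± 8.3 FPKM, a log2 fold change of -0.73 ± 0.024 (edgeR adjusted p = 0.000138). Both lists passed camera (adjusted p = 2.86e-20 for HIF targets and 3.95e-15 for glycolysis). The HIF call was lost with an estimated correlation (adjusted p = 0.0707), and the glycolysis call held (adjusted p = 0.0266).

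**Figure D2:**
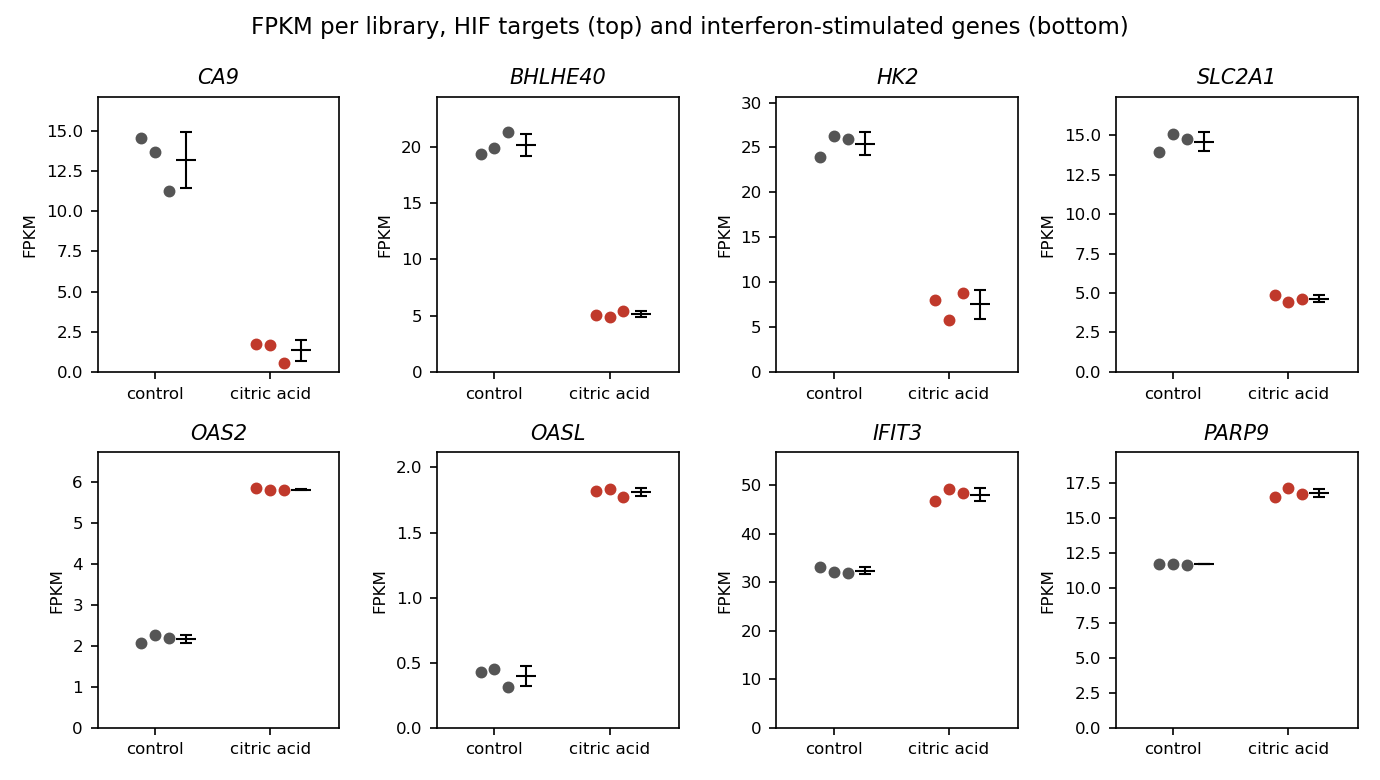
FPKM (linear axes from 0) in each of the 3 control (grey) and 3 citric acid (red) libraries, with the group mean and SD as black bars. The top row shows HIF targets or glycolytic genes, with CA9 falling from 13.2 to 1.33 FPKM, and the bottom row interferon-stimulated genes, with OAS2 rising from 2.18 to 5.82 FPKM.

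Genes of ribosome assembly, DNA replication and protein folding fell by smaller amounts. In the ribosome biogenesis list 31 of 35 genes were lower and none higher, 33 adjusted over the list alone, with a median log2 fold change of -0.58. DDX21, a nucleolar helicase, fell from 88.0 ± 1.3 to 56.2 ± 1.0 FPKM, and TSR1, NCL and NOP56, which serve ribosome assembly, had log2 fold changes of -0.91, -0.56 and -0.75. The G1/S and DNA replication list had 25 of 35 genes lower and 2 higher, as it did adjusted over the list alone. FEN1, the flap endonuclease, fell from 68.6 ± 1.8 to 41.7 ± 1.5 FPKM, and the helicase subunits MCM6 and MCM7 and the replication factor GINS2 had log2 fold changes of -0.50, -0.46 and -0.66. In the G2/M list 16 of 35 genes were lower and 1 higher, 18 and 1 adjusted over the list alone, among them the mitotic genes PLK1, UBE2S, CDC20 and HMMR at -0.42, -0.34, -0.31 and -0.43. The heat shock list had 13 of 19 genes lower and none higher, also adjusted over the list alone. HSP90AA1 and HSP90AB1, the cytosolic HSP90 chaperones, and the chaperone genes HSPH1 and AHSA1 had log2 fold changes of -0.71, -0.57, -0.80 and -0.58. Of 66 cytosolic ribosomal protein genes 1 passed the test, RPS3A at 0.69, and none adjusted over the list alone, and that call was lost without control replicate 1 (edgeR adjusted p = 0.0586) and without citric acid replicate 2. Camera adjusted p-values were 1.70e-20 for ribosome biogenesis, 1.87e-10 for G1/S, 0.000254 for G2/M and 9.37e-07 for heat shock. With an estimated correlation the first 2 calls held, each with adjusted p = 0.0417, and the G2/M (adjusted p = 0.163) and heat shock (adjusted p = 0.122) calls did not. The G2/M call was also lost with quantile normalization (adjusted p = 0.121).

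Interferon-stimulated genes rose in 20 of 24 tested cases and fell in none, 21 adjusted over the list alone, with a median log2 fold change of 0.76. OAS2 and OASL, of the oligoadenylate synthetase family, rose by 1.38 and 2.13 on the log2 scale, OAS2 from 2.18 ± 0.099 to 5.82 ± 0.025 FPKM. IFIT3, an antiviral effector, rose from 32.4 ± 0.68 to 48.1 ± 1.3 FPKM, and PARP9 by 0.48 on the log2 scale. Of 24 tested p53 targets 14 were higher and 1 lower, 16 and 1 adjusted over the list alone, with a median of 0.37. BTG2, an antiproliferative gene, rose from 10.5 ± 0.83 to 20.3 ± 0.59 FPKM, and TP53INP1, SESN2 and CCNG1 had log2 fold changes of 0.90, 0.46 and 0.36. Transcripts of the mitochondrial genome rose in 6 of 15 cases, 9 adjusted over the list alone, with MT-RNR2, the large ribosomal RNA, at 0.70 and MT-CO1, MT-ND5 and MT-ND6, genes of the respiratory chain, at 0.24, 0.32 and 0.40. Camera adjusted p-values were 4.88e-12 for interferon-stimulated genes, 3.35e-06 for p53 targets and 0.00588 for mitochondrial transcripts. With an estimated correlation p53 targets held (adjusted p = 0.0417), while interferon-stimulated genes (adjusted p = 0.0707) and mitochondrial transcripts (adjusted p = 0.446) did not. Quantile normalization turned the direction of the mitochondrial list and ended the single-gene calls of MT-CO1, MT-ND5 and MT-ND6. The MT-CO1 call was also lost in limma without a filter.

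**Figure D3:**
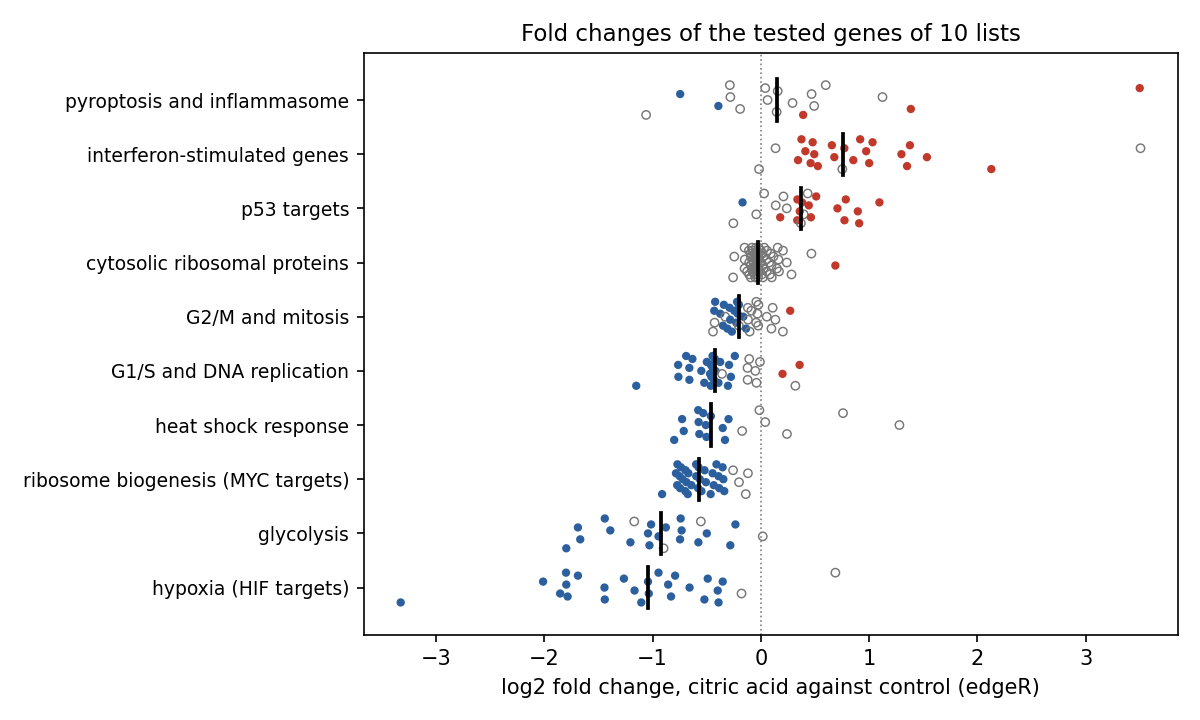
Log2 fold changes of citric acid against control (edgeR) for the tested genes of 10 lists fixed before the data were examined; each point is a gene, filled red (higher) or blue (lower) where the adjusted p is under 0.05 and open otherwise, and black bars are list medians. Medians are -1.04 for HIF targets and 0.76 for interferon-stimulated genes.

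A further 5 lists were lower. In the immediate early list 11 of 28 genes were lower and 2 higher, 12 and 4 adjusted over the list alone. DUSP6, a phosphatase of ERK, fell from 66.6 ± 0.55 to 33.7 ± 1.5 FPKM, and the transcription factor genes EGR1, FOSL2 and NR4A1 had log2 fold changes of -1.76, -1.53 and -1.09. In the NRF2 list 9 of 23 were lower and none higher, also adjusted over the list alone, with HMOX1, heme oxygenase 1, at -0.67 and ABCC1, TKT and PGD at -0.29, -0.22 and -0.37. Among cholesterol biosynthesis genes 9 of 24 were lower and 2 higher, 12 and 2 adjusted over the list alone: FDPS, HSD17B7 and ACAT2 had log2 fold changes of -0.39, -0.86 and -0.48 and TM7SF2 rose by 0.64. In the unfolded protein response list 11 of 27 were lower and 1 higher, 12 and 2 adjusted over the list alone. SDF2L1, DNAJB11 and HYOU1, which serve folding in the endoplasmic reticulum, were at -0.62, -0.33 and -0.25 and the stress sensor ATF6 at 0.34. In the zinc and copper list 3 of 9 were lower and none higher, also adjusted over the list alone. These were SLC39A6, MTF1 and SLC30A1, 2 metal transporters and a metal-sensing factor, at -0.56, -0.35 and -0.34, while the metallothionein MT1F was at -0.90 without passing the test (edgeR adjusted p = 0.0993). The MTF1 and SLC30A1 calls ended without single libraries (edgeR adjusted p of up to 0.0741 and 0.0959), and the list call without control replicate 1 (camera adjusted p = 0.0695), in limma on log2(FPKM + 1) (0.103), with a replicate block (0.0528) and with counts divided by 4 (0.0788). Camera adjusted p-values were 0.00201, 0.00588, 0.00708, 0.0114 and 0.0265 in the order given, and none of the 5 calls held with an estimated correlation (adjusted p = 0.101, 0.106, 0.163, 0.117 and 0.202). With a mean FPKM of at least 5 required, the direction of the immediate early list turned (camera adjusted p = 0.495), and the NRF2 (0.101), cholesterol (0.330) and unfolded protein response (0.151) calls were lost. The immediate early call was also lost in limma on log2(FPKM + 1) (0.0912), and the cholesterol (0.0535) and unfolded protein response (0.163) calls with quantile normalization.

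Camera called 14 of the 31 lists, 3 higher and 11 lower. With an estimated correlation it called 4, 1 higher and 3 lower. The lists outside the 14 did not pass camera, though each held genes that passed the test. In the integrated stress response list 5 of 39 genes were higher and 13 lower (camera adjusted p = 0.327), with NUPR1 and ALDH1L2 at 0.97 and 0.66. Fatty acid synthesis had 5 of 18 higher and 5 lower (0.699), with ACLY, which cleaves citrate to acetyl-CoA, falling from 71.1 ± 0.47 to 50.4 ± 1.2 FPKM and the desaturase SCD from 161 ± 4.4 to 123 ± 2.2 FPKM. The citrate cycle list had 2 of 25 higher and 6 lower (0.376), with IDH2, mitochondrial isocitrate dehydrogenase, rising from 60.2 ± 1.8 to 105 ± 1.5 FPKM and DLAT at -0.28. Citrate and monocarboxylate transport and acid sensing had 2 of 17 higher and 6 lower (0.123), with the lactate exporter SLC16A3 at -1.67 and the carbonic anhydrase CA12 at -1.73, and was called lower in limma on log2(FPKM + 1) (0.0149) and without control replicate 3 (0.0378). Iron homeostasis had 4 of 17 higher and 3 lower (0.327): the transferrin receptor TFRC fell from 35.0 ± 0.72 to 16.4 ± 0.63 FPKM and the iron reductase CYBRD1 rose from 6.68 ± 0.29 to 12.5 ± 0.29 FPKM. The glucose-sensing list around TXNIP had 3 of 10 higher and 3 lower (0.955), with MLX, the partner of MondoA, at -0.49. Apoptosis regulators had 4 of 29 higher and 5 lower (0.519), with BMF, a BH3-only killer gene, at 2.59 and BID at -0.54. BMF was low, at 0.0627 ± 0.0089 FPKM in control and 0.398 ± 0.078 FPKM in citric acid. The inflammatory cytokine list had 3 of 17 higher and 2 lower (0.694), with the chemokine CCL5 rising from 0.0321 ± 0.030 to 1.28 ± 0.17 FPKM and BIRC3 at 1.33. BIRC3 was at 0.174 ± 0.035 FPKM in control, and its call was lost with a replicate block.

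In the lysosome and autophagy list 7 of 32 genes were higher and 5 lower (camera adjusted p = 0.441), with the autophagy genes ULK1 and GABARAPL1 at 0.92 and 1.02. Epithelial, mesenchymal and matrix genes had 13 of 38 higher and 8 lower (0.206), with ACTA2, smooth muscle actin, rising from 22.8 ± 0.96 to 44.6 ± 1.1 FPKM and COL3A1 at 0.49. This list was called higher in limma on log2(FPKM + 1) (camera adjusted p = 0.0452) and at a mean FPKM of at least 5 (0.00493). The nuclear respiratory chain had 7 of 35 lower (0.141), with UQCRFS1 and ATP5MC1 at -0.29 and -0.35, and was called lower after TPM (0.00760) and median-ratio (0.0304) scaling, without control replicate 2 (0.0280) and on log2 CPM (0.0410). Histone genes had 1 of 10 higher and 4 lower (0.443), with H1-2 at -0.67. Of the RNA quality list 1 of 7 was higher (0.923), GAS5 at 0.46. Of the leukocyte markers 4 of 16 reached the filter, with CD74 at 1.48 from 0.311 ± 0.037 FPKM and CD68 at -1.10 (0.416), and the CD68 call ended without single libraries (edgeR adjusted p of up to 0.109). Of the fibroblast, endothelial and blood markers 2 of 7 were higher and 2 lower (0.739), with PDGFRB at 1.37 from 0.147 ± 0.036 FPKM and PDGFRA at 0.20. Adjusted over the list alone, the higher and lower counts in the order given were 6 and 14, 5 and 5, 4 and 8, 2 and 6, 6 and 3, 3 and 4, 4 and 5, and 3 and 2 for the lists from integrated stress to cytokines. From lysosome to fibroblast markers they were 7 and 5, 13 and 9, 0 and 6, 3 and 4, 1 and 1, 1 and 1, and 2 and 2. The median, mean and camera direction differed in sign for fatty acid synthesis, glucose sensing, ribosomal proteins, histones and RNA quality.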

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

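The tests with RLE factors, library size alone, without mitochondrial genes, counts divided by 4, robust fits and camera on log2 CPM were chosen after the data were seen. DESeq2 called 5382 genes, including 4597 of the 4660, and edgeR without its filter called 3776. The count of changed genes fell to 2648 with a mean FPKM of at least 5, where 6257 genes were tested, and ran from 3169 to 3700 without single libraries. Of the called genes 5 changed direction with quantile normalization, 1 with summed rows and none in the other alternatives. Counts of at least 2-fold changes were far lower with limma on FPKM: 122 with a pseudocount of 1, 290 with 0.1, 112 without a filter, 72 at a mean of at least 5, 203 on the TPM scale, 117 with median ratios, 116 with quantile normalization and 122 without the variance trend. In the same order, the counts at an unadjusted p under 0.05 were 135, 326, 134, 79, 235, 130, 130 and 130. Limma without the filter gave 112, but with a pseudocount of 1 genes under 1 FPKM in both groups cannot reach 2-fold. That fit therefore cannot tell whether the filter plays a part. On the same 11816 genes, a pseudocount of 0.1 in place of 1 raised the count from 122 to 290. Other causes were not separated. In edgeR without single libraries the 2 counts, 786 and 1192 in full, ran from 611 to 714 and from 1183 to 1295. The split of 2182 higher and 2478 lower in edgeR turned to 2485 and 2168 with library size alone. In limma it was 2163 and 2064 on FPKM as deposited and 1477 and 2620 on the TPM scale. At least 2-fold changes kept an excess of rises in edgeR under each scaling. In limma they were 60 higher and 62 lower with a pseudocount of 1 and 173 and 117 with 0.1. No scaling moved the median of all tested genes by over 0.1. The pyroptosis list had 3 changed genes at a mean FPKM of at least 5, and 3 to 5 without single libraries. Camera called 4 lists with an estimated correlation and fry 25, and 13 to 15 lists were called without single libraries. Quantile normalization added a call of ribosomal proteins as higher (camera adjusted p = 0.000177). The lists were not run with DESeq2, summed rows, RLE factors, library size alone, robust dispersion fits or robust eBayes without trend. Of 111 named genes tested, 92 kept their side of the threshold in each alternative that tested them, and none changed direction. TKT and HYOU1 lost their calls with quantile normalization, PGD in limma on FPKM without a filter and PDGFRA on the TPM scale. Some genes of low level were tested in fewer alternatives: GSDMD in 12, and BMF, CCL5, CD74 and PDGFRB in 16 each. The labels do not say whether a shared replicate number marks a shared culture or day. Same-number libraries deviated with correlations of -0.035, -0.039 and -0.023, which show no sign of pairing but cannot exclude it. With a replicate block edgeR called 2883 genes, 521 at least 2-fold, and the cause of the lower counts was not tested. Depth limits the genes near 0, such as GSDMD and NLRP3.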

Other observations

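The tests of HIF targets outside glycolysis and of leukocyte transcripts, and the tests of annotated terms, were chosen after the results were seen. Among the 10 KEGG terms enriched in genes lower in citric acid, the strongest was ribosome biogenesis, with 46 of 73 genes lower where 14.3 were expected (Fisher's exact test, adjusted p = 1.05e-13). Of 129 spliceosome genes 59 were lower (adjusted p = 1.22e-09), of 149 RNA transport genes 60 (adjusted p = 2.9e-07), of 118 cell cycle genes 48 (adjusted p = 5.93e-06), of 31 RNA polymerase genes 18 (adjusted p = 0.00012) and of 43 proteasome genes 22 (adjusted p = 0.00014). Of 25 pentose phosphate pathway genes, which make NADPH and ribose, 14 were lower (adjusted p = 0.00214). For genes higher in citric acid, the 2 KEGG terms past the threshold were Staphylococcus aureus infection, with 12 of 27 genes (adjusted p = 0.0175), and Jak-STAT signaling, with 26 of 100 (adjusted p = 0.0479). For lower genes 190 GO terms passed, led by rRNA processing with 99 of 164 genes (adjusted p = 6.92e-33). They include positive regulation of type I interferon production, with 24 of 47 genes lower where 7.91 were expected (adjusted p = 9.99e-06). The strongest of the 17 GO terms for higher genes were antiviral: 47 of 144 genes of defense response to virus were higher, where 18.9 were expected, and 23 of 46 of type I interferon signaling (adjusted p = 3.17e-06 each). Other GO terms for higher genes were collagen-containing matrix, with 55 of 222 genes (adjusted p = 0.00117), and the lysosomal lumen, with 24 of 77 (adjusted p = 0.0104). Genes were treated as independent in these tests.

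In the splits of the 6 libraries into 3 and 3, 1 of 10, the real one, gave as many genes as observed. The real split called 4660 genes and the highest other split 4, and for at least 2-fold changes the values were 786 and 4. The real split called 14 lists and the highest other split 11. The other splits each mix 2 libraries of a group with 1 of the other, so they keep part of the difference and are not values without an effect. With 10 splits no share under 0.05 can be reached.

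HIF target and glycolysis genes were lower in citric acid. The fitted trend with GC content and transcript length was weak, at most 0.21 on the log2 scale for any gene and 0.0469 for a HIF target. Removing it left the HIF median at -1.06 (95% bootstrap interval over genes -1.46 to -0.76). Each interval in this paragraph resampled the genes of a list as if independent and does not measure the spread between libraries. Over 4 scalings the highest HIF median was -1.005. These scalings differed little, with medians of all tested genes from 0.014 to 0.050. Neither the fitted trend nor a choice among these 4 scalings accounts for the fall. Whether lower HIF activity is behind it stays open: HIF targets outside the glycolysis list had a median of -0.86, but that 19 of these 21 were lower follows from the 24 of 26 in the full list and is no separate evidence. Lower PI3K-AKT-mTOR signalling may also lower these genes and predicts higher FOXO targets; of 13 tested FOXO targets, 5 were higher and 1 lower, with a median of 0.27 (interval -0.24 to 0.37; camera adjusted p = 0.286), so this stays open too. That list was written after the main results and before its members' values were seen, and left out TXNIP, SESN1, GABARAPL1 and KLF6, whose values had been seen, so it does not measure FOXO targets as a whole.

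Interferon-stimulated genes were higher in citric acid. Leukocytes would bring their abundant transcripts, but 1 of 8, NKG7, had counts in all 3 citric acid libraries, and no mean exceeded 0.334 FPKM. The fitted trend with GC content and transcript length was at most 0.0509 for a gene of the list. Removing it left the median at 0.74 (95% bootstrap interval over genes, taken as independent, 0.48 to 0.98). PTPRC, LYZ, S100A8 and CD14 had a count of 0 in all 3 citric acid libraries, which argues against leukocyte RNA. The 8 transcripts were chosen after the results were seen, however. They leave out CD74 and CD68 of the list fixed beforehand, with log2 fold changes of 1.48 and -1.10. NKG7 had counts of 17, 15 and 8 in control and 19, 18 and 33 in citric acid. The fitted trend was too weak to account for the rise, and other technical causes were not tested. An interferon-type response of the cells to citric acid remains a hypothesis.

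TXNIP was higher in citric acid. TXNIP may rise through MondoA, a transcription factor that senses glucose phosphates and acid, which predicts a rise of its other strong target ARRDC4. ARRDC4 rose from 0.163 ± 0.058 to 1.23 ± 0.084 FPKM, a log2 fold change of 2.84 ± 0.27 (edgeR adjusted p = 0.0011), in line with this hypothesis. The wider list of glucose sensing fixed beforehand did not pass camera (adjusted p = 0.955), while fry called it higher (adjusted p = 4.22e-05). Of its genes 3 of 10 were higher and 3 lower, with a median of -0.08. MLX, the partner of MondoA, fell by 0.49 on the log2 scale. The list holds TXNIP and ARRDC4 themselves and mixes regulators with targets, so neither list test measures MondoA targets alone. An effect of acid cannot be separated from an effect of citrate, since no acid-matched group was analysed here.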
